A study of Mus musculus with 24 samples.

How the data were processed

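RNA sequencing had been run on primary mouse embryonic fibroblasts (MEFs, cells grown out of dissociated embryos) of the C57BL/6 strain, either wild type (WT) or lacking cGAS, the cytosolic DNA sensor encoded by Mb21d1 (KO). Per the labels, RNA was taken on days 33, 36 and 42 of culture under 20% oxygen, extracted on silica columns and made into stranded, poly(A)-selected libraries. The labels list 4 numbered samples for each genotype and day, which gave 24 columns in each of the deposited tables.

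The authors deposited estimated counts per gene and per transcript, which are fractional and not normalized, per the file headers and the values. The deposited gene table also gives RPKM values, per the file headers. These were used only to derive a total for each column. Expression was taken from the estimated counts, because they carry the depth. A further 24 columns of per-sample values in the transcript table were not used. The submitters' processing notes name the mouse build mm10, Bowtie2 2.2.1 and limma 3.18.13 without their roles. The counting program, the annotation release and the strand setting are not given in the sources used here. Reads of near-identical genes could therefore be split between copies, and values of Lyz1 and Lyz2, Prl2c2 and Prl2c3, and Ifit3 and Ifit3b are uncertain for that reason. Tsix, antisense to Xist, had 0 counts in all 6 libraries while Xist reached 25267 counts in one of them.

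The 4 columns of a group were compared before any averaging. Over 12385 to 13738 genes with at least 80 counts in a group, the mean chi-square per degree of freedom between the 4 columns was 0.832 to 0.843, and 3.38 to 3.63% of genes had an unadjusted p below 0.05. Among genes with over 10000 counts the mean was 0.996 to 1.05. The same statistic between a column of WT day 33 and a column of another group was 11.7 to 60.8. Column totals, derived from the counts, gene lengths and RPKM values, also stood in nearly the same ratio in all 6 groups. Number 2 held 0.991 to 0.997 times the total of number 1. Number 3 held 1.022 to 1.026 times and number 4 held 1.018 to 1.025 times. The 4 columns of each group thus agreed within sampling noise and were summed and counted as 1 library, leaving 6 libraries, 3 per genotype and 1 per genotype and day.

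This changed the design. Before the data were examined, the tests had been written for 24 separate libraries in 6 groups of 4. That fit is given only as an alternative, because its p-values would measure the sampling noise of 1 library and not the spread between cultures. The comparison left with replication was KO against WT over the 3 days, in which the days serve as replicates; since nothing in the labels says that the days are separate cultures, its p-values measure only the spread between these libraries, which may be technical or come from 1 culture line per genotype. For comparisons between single libraries no p-value is given.

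Summed counts were rounded to whole numbers. Of 45706 genes in the table, 28938 had a count in any library and 17233 passed edgeR's filterByExpr. KO and WT were compared with edgeR 4.0.16 (TMM factors 0.927 to 1.08, robust quasi-likelihood test, genotype as the term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other size factors, filters, leaving out libraries, days or columns, and a replicate block. The fit of 24 columns was the design written beforehand and became an alternative after the data were seen. The fit of 6 summed libraries, day as a factor and a test of time over both genotypes were chosen after the data were seen. The other alternatives were written beforehand for 24 libraries and applied to the 6 where they fit.

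Between single libraries, genes were counted that differed at least 2-fold on the log2 CPM scale and reached 5 CPM in the highest library. CPM are counts scaled to the library total times its TMM factor, and log2 CPM had a prior count of 2. The 24 gene lists had been fixed before the data were examined. Over the 3 days they were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over lists. Between single libraries the median log2 difference of a list is given as a percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries. Counting intervals are exact 95% intervals and cover counting error only.

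Genes named in the text follow a rule fixed beforehand: the 10 largest differences each way over the 3 days and the 5 largest each way in other comparisons (at least 5 CPM, no predicted names, the same sign on all 3 days for the former), up to 4 members of each list by adjusted p, and a set of genes named in advance. Between single libraries the adjusted p in that rule was replaced by the 2-fold minimum. Fos and the genes called in every fit that left out 1 library were named after their values were seen. Some genes that meet this rule are not reported here. Coordinates are 1-based on mm10 from GENCODE M21, in which 45143 of the 45706 gene identifiers were found. Log2 values are rounded to 2 decimals and other values to 3 significant digits.

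The procedure was tested on simulated counts. With 17075 genes and 3 libraries against 3, the test for KO against WT over 3 days recovered 51.5% of 99 genes changed 2-fold and 98% of 100 genes changed 4-fold, with 11 false calls among 160. For KO against WT at day 33, counts were simulated with counting noise alone (Poisson). The count of genes by fold over 11674 genes then recovered 36 of 72 genes changed 2-fold, which lie at the threshold, and 78 of 78 changed 4-fold. Of unchanged genes 0 passed. Spread between libraries was not simulated there, so the 0 does not show how many unchanged genes such spread would push past 2-fold.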

Results

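The transcriptomes of WT and cGAS KO MEFs were compared at 3 late time points of serial culture, in a series whose title concerns cGAS and senescence, the lasting growth arrest of stressed or aged cells. The 4 columns deposited for each genotype and day agreed within sampling noise and were counted as 1 sample, so that n = 1 library per genotype and day and n = 3 libraries per genotype. The WT libraries of days 33, 36 and 42 held 48716880, 47091985 and 35024528 counts, and the KO libraries 33635944, 25650577 and 36447008. Mitochondrially encoded transcripts took 1.88, 2.38 and 1.1% of the WT counts and 1.27, 0.694 and 0.889% of the KO counts (exact Clopper-Pearson 95% interval 2.376 to 2.385% for WT day 36 and 0.691 to 0.698% for KO day 36, counting error only). Values are CPM (the count divided by the library total, scaled), given as mean ± SD over the 3 days, and log2 fold changes are KO over WT ± SE. This SE was derived as the absolute log2 fold change divided by the square root of the test's F statistic. It is approximate, above all for genes with low counts.

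Mb21d1 (ENSMUSG00000032344, chromosome 9, 78430526 to 78443237, minus strand), the targeted gene, was at 4.74, 4.08 and 4.82 CPM in WT and at 0.239, 0 and 0.127 CPM in KO on days 33, 36 and 42. Summed over days, 568 counts in WT stood against 13 in KO, 34.7-fold lower (counting interval 20.1 to 65.7). The log2 fold change was -5.11 ± 0.62 (n = 3 per genotype, adjusted p = 0.0102 by edgeR's quasi-likelihood test), a call that was lost without the KO library of day 42, at -5.10. The labels of all 6 libraries therefore matched the level of the targeted gene. Among the 18 measured genes of the cGAS-STING pathway, 2 rose and 2 fell (4 and 4 adjusted over the list alone). Banf1, a chromatin-binding protein that restrains cGAS, rose by 0.38 ± 0.08 (adjusted p = 0.0351), and Mavs, the adaptor of RNA sensing, had a log2 fold change of -0.37 ± 0.08 (adjusted p = 0.0446). Nlrc3 rose by 0.67 ± 0.15; the calls of these 3 genes were lost with day as a factor. Tmem173, which encodes STING, was at 31.1 ± 9.12 CPM in WT and 36.3 ± 5.93 in KO (adjusted p = 0.60). The list had a median of 0.05, a mean of -0.34 and a camera direction upward (adjusted p = 0.983). Only 1 member was called without WT day 33, WT day 36, KO day 33 or KO day 36, 0 without KO day 42, and 2 higher and 1 lower without WT day 42.

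Over the 3 days KO cells had more transcripts of cell division genes and less of the cell cycle inhibitors Cdkn2a, Cdkn2b and Cdkn1a than WT cells. The list of cell division genes was not called by camera with an estimated correlation (adjusted p = 0.333), and another inhibitor, Cdkn1b, was higher in KO (adjusted p = 0.00897). Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes p16Ink4a and p19Arf, was at 98.0 ± 12.1 CPM in WT and 40.7 ± 3.34 in KO (log2 fold change -1.27 ± 0.12, adjusted p = 0.00824). Homeobox genes, the chemokines Ccl2 and Ccl7 and Y-linked genes were lower in KO, and Xist, Lif and Igfbp2 were higher. By edgeR's quasi-likelihood test 1503 of 17233 genes differed at an adjusted p below 0.05, 701 higher and 802 lower in KO, of which 205 and 513 differed at least 2-fold. All 1503 had the same sign on the 3 days, which a call on these same libraries nearly forces and which is no further support. An unadjusted p below 0.05 was found for 4700 genes, and the 3 values of each genotype did not overlap for 34.3% of genes, against 10% by chance. The count rested on single libraries: it was 254 without WT day 33, 738 without WT day 36, 24 without KO day 36, 68 without KO day 42, 1703 without WT day 42 and 1811 without KO day 33. It was 429, 3 and 539 without days 33, 36 and 42, and 2855 by DESeq2. With day as a factor 1338 genes were called, 1063 of them among the 1503. The higher share of the calls was 46.6%, but 8.33% without KO day 36, 26.5% without KO day 42 and 0% without day 36.

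A total of 22 genes were called in each of the 6 fits that left out 1 library, 20 lower and 2 higher in KO. They included Xist and the Y-linked Uty, Eif2s3y, Kdm5d and Ddx3y, and on the autosomes Rpl39l, Pla2g7, Hoxc6, Gsta4 and Ctsk. Others were Tnfaip8, Fgf13, Prl2c2, Prl2c3, Apcdd1, Dhrs9, P2rx3, Brinp1, Olr1, Gm2115 and Galnt18.

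Cell proliferation genes rose as a group: 43 of 50 measured members were higher in KO, 0 were lower and 7 were not called (47 higher and 1 lower adjusted over the list alone; median log2 fold change 0.72; camera adjusted p = 6.06e-25, and adjusted p = 0.333 with an estimated correlation). Birc5, an inhibitor of apoptosis that acts in chromosome segregation, rose from 21.2 ± 0.26 to 39.7 ± 2.26 CPM (0.91 ± 0.08, adjusted p = 0.00755). Uhrf1, which maintains DNA methylation, rose by 1.22 ± 0.11, Ccna2, the S and G2 phase cyclin, by 0.97 ± 0.10, and Plk1, a mitotic kinase, by 0.72 ± 0.08. Mki67, the marker of cycling cells, was at 149 ± 9.59 CPM in WT and 260 ± 31.2 in KO (0.80 ± 0.11, adjusted p = 0.0142). By single day, 48, 49 and 49 of the 50 members were higher in KO. The number called was 0 without KO day 36, 2 without KO day 42, 7 without WT day 33 and 23 without WT day 36.

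Of the 21 senescence and cell cycle inhibitor genes, 3 rose, 4 fell and 14 were not called (5 and 4 adjusted over the list alone). Besides Cdkn2a, Cdkn2b (p15Ink4b) fell from 58.8 ± 2.87 to 17.0 ± 6.93 CPM (-1.79 ± 0.27, adjusted p = 0.0169) and Cdkn1a (p21), a p53 target, from 558 ± 49.4 to 336 ± 70.2 CPM (-0.73 ± 0.17, adjusted p = 0.0478). Cdkn1b, which encodes the inhibitor p27, went the other way, from 36.5 ± 3.63 to 70.7 ± 2.52 CPM. Lmnb1, the nuclear lamin lost in senescent cells, rose by 0.91 ± 0.14 (adjusted p = 0.0159), and Ezh2, a histone methyltransferase, by 0.81 ± 0.12. The list's median was 0.09, its mean -0.08 and its camera direction upward (adjusted p = 0.873). Transcripts of the p16Ink4a form of Cdkn2a were at 46.4, 47.2 and 38.6 CPM in WT and 20.4, 21.5 and 18.9 in KO, and those of the p19Arf form at 49.3, 39.1 and 40.4 against 16.4, 21 and 19.7. These transcript values were scaled to the total over all transcripts without TMM factors, so they are not on the scale of the gene values. Each form differed with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Without KO day 36 or KO day 42, 0 of the 21 genes were called, without WT day 33 there were 1 higher and 1 lower, and without WT day 36 the numbers were 3 and 3.

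**Figure D1:**
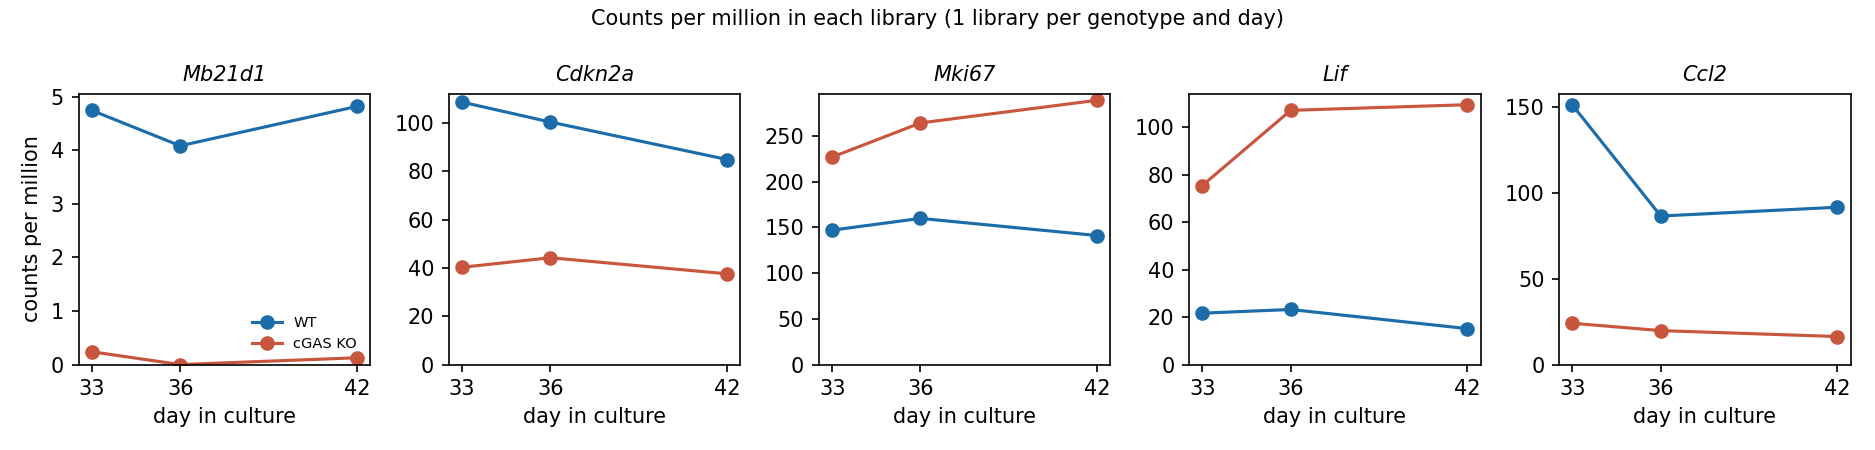
CPM (vertical axes, from 0) of Mb21d1, Cdkn2a, Mki67, Lif and Ccl2 against the day in culture, 1 point per library, WT in blue and KO in red; lines join the days and there are no error bars because each point is 1 library. Cdkn2a lies between 84.9 and 109 in WT and between 37.6 and 44.2 in KO, and Lif between 15.2 and 23.2 in WT and between 75.5 and 110 in KO.

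Secreted factors associated with senescence moved in both directions. Of 40 measured, 4 rose, 7 fell and 29 were not called (6 and 11 adjusted over the list alone; median -0.63; camera adjusted p = 0.00793, and adjusted p = 0.81 with an estimated correlation). Lif, a cytokine of the IL-6 family, rose from 20.0 ± 4.28 to 97.4 ± 19 CPM (2.28 ± 0.22, adjusted p = 0.00857), and the growth factor binding protein Igfbp2 from 313 ± 175 to 2812 ± 905 CPM (3.17 ± 0.52, adjusted p = 0.0208). The monocyte chemokines Ccl2 and Ccl7 had log2 fold changes of -2.45 ± 0.27 and -2.68 ± 0.40, and Igfbp6 one of -3.76 ± 0.47. Macrophage markers were also lower in KO, by medians of -1.16, -3.84 and -1.05 on days 33, 36 and 42 (1 library per genotype and day); on day 42 most of these markers were near 0 in both genotypes, so that the median of that day leans on the prior count. Il6 was at 3.54, 4.36 and 2.95 CPM in WT and 12.6, 1.90 and 0.583 in KO (adjusted p = 0.798). The matrix protease Mmp3 was at 6.49, 1.35 and 10.3 CPM in WT and 3.05, 0.112 and 0 in KO (adjusted p = 0.318). The numbers called were 0 without KO day 36, 1 higher without KO day 42, 2 higher and 2 lower without WT day 33, 1 and 5 without WT day 36, and 2 and 15 without KO day 33.

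Interferon-stimulated genes were not called as a group over the 3 days. Of 39 measured, 0 rose and 1 fell (0 adjusted over the list alone), Ifi27l2a at -3.62 ± 0.71 (adjusted p = 0.0324). It rests on low counts, 135 in WT against 8 in KO over the 3 days. An unadjusted p below 0.05 was found for 8 members, and camera gave an adjusted p of 0.0731 (median -0.43). Lgals3bp (adjusted p = 0.0667) and the RNA sensor Ifih1 (adjusted p = 0.0974) had log2 fold changes of -1.48 ± 0.39 and -0.77 ± 0.24, and the GTPase Irgm1 one of 0.90 ± 0.22 (adjusted p = 0.0536). Isg15 was at 1.39 ± 0.95 CPM in WT and 1.01 ± 0.31 in KO (adjusted p = 0.632). Cxcl10 lay below the expression filter with 16, 10 and 41 counts in WT and 5, 5 and 10 in KO, and Ifnb1 had 0 counts in all 6 libraries.

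Of 34 p53 target genes, 1 rose and 4 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.00933, and adjusted p = 0.702 with an estimated correlation). Perp, a p53 effector and desmosome protein, rose by 1.48 ± 0.27 (adjusted p = 0.0277), and Ephx1, Polk and Ercc5 had log2 fold changes of -0.79 ± 0.18, -0.61 ± 0.14 and -0.44 ± 0.10; the calls of Perp, Ephx1 and Ercc5 were lost with day as a factor. Trp53 was at 67.5 ± 5.38 CPM in WT and 85.4 ± 9.22 in KO (adjusted p = 0.111), and Mdm2, which degrades p53, at 336 ± 92.7 and 198 ± 36.5 (adjusted p = 0.104). Of 25 NRF2 antioxidant genes 1 rose and 5 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.0279, and adjusted p = 0.81 with an estimated correlation), among them Gsta4 at -2.34 ± 0.19 (adjusted p = 0.00643), Nqo1 at -1.04 ± 0.12, the ferritin gene Fth1 at -0.91 ± 0.11 and Srxn1 at -0.88 ± 0.13. Gsta4 lies beside the targeted Mb21d1 on chromosome 9 (78182774 to 78209349), and an effect of the targeted locus on it was not tested. Without KO day 36, 0 p53 targets and 1 NRF2 gene were called, and without KO day 42 again 0 and 1. Without WT day 33 the numbers were 0 and 3, and without WT day 36 they were 2 and 5.

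Matrix and contractile genes were lower for some members. Of 40 extracellular matrix genes 3 fell and 0 rose (9 lower adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.81 with an estimated correlation): Thbs2, an inhibitor of angiogenesis, at -1.46 ± 0.27, and the collagen chains Col12a1 and Col6a3 at -1.42 ± 0.32 (not called with day as a factor) and -1.0 ± 0.22. Of 19 contractile and myofibroblast genes 1 rose and 3 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.00287, and adjusted p = 0.81 with an estimated correlation), with Cnn1 at -1.86 ± 0.38, Lmod1 at -1.06 ± 0.12, Myh11 at -0.71 ± 0.14 and Smtn at 0.59 ± 0.12. Without KO day 36, 0 genes of either list were called, and without KO day 42 there were 0 and 1. Without WT day 33 the numbers were 0 and 1, without WT day 36 they were 3 and 1, without KO day 33 10 matrix genes were lower, and without WT day 42 3 matrix genes were higher and 1 lower.

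HOX genes, the transcription factors that record position along the body axis, fell as a group. Of 35 measured, 19 were lower and 1 higher in KO, with a median of -2.36 (20 and 5 adjusted over the list alone; camera adjusted p = 1.68e-07, and adjusted p = 0.496 with an estimated correlation). Hoxc6 fell from 39.9 ± 7.43 to 5.42 ± 1.32 CPM (-2.89 ± 0.22, adjusted p = 0.00638), and Hoxc5, Hoxd9 and Hoxd1 had log2 fold changes of -2.88 ± 0.29, -2.66 ± 0.28 and -3.01 ± 0.29. By cluster, 7 of 7 measured Hoxc genes, 5 of 9 Hoxd, 4 of 8 Hoxb and 3 of 11 Hoxa genes were lower, and the median of the Hoxa cluster was 0.46. Of paralogues 1 to 8, 12 of 22 were lower, and of paralogues 9 to 13, 7 of 13. The number of lower HOX genes was 1 without KO day 36, 4 without KO day 42, 7 without WT day 33 and 12 without WT day 36. Of the 17 HOX genes with a mean of at least 5 CPM, 8 were lower and 1 higher, with a median of -1.15.

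The sex-linked transcripts separated the genotypes on every day. Xist, the RNA that silences an X chromosome in female cells, was at 0.363, 0.183 and 0.057 CPM in WT and at 479, 465 and 641 CPM in KO (11.26 ± 0.44, adjusted p = 0.000503; 2502-fold by summed counts, counting interval 1720 to 3797). The Y-linked genes were lower in KO but present there. Uty was at 30.9 ± 1.04 CPM in WT and 2.83 ± 0.13 in KO (-3.45 ± 0.10, adjusted p = 0.000174), and Eif2s3y, Kdm5d and Ddx3y had log2 fold changes of -3.23 ± 0.13, -2.48 ± 0.13 and -1.84 ± 0.14. All 5 measured members were called, 4 lower and 1 higher (4 and 1 adjusted over the list alone; median -2.48, mean 0.05, camera downward with adjusted p = 0.00103, and adjusted p = 0.333 with an estimated correlation). The same 4 and 1 were called when any single library was left out, and 1 lower gene without day 36.

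Genes with the largest differences that were higher in KO included the epithelial adhesion genes Lad1 and Pkp1 (4.94 ± 1.03 and 3.48 ± 0.39), Wnt16 (3.33 ± 0.68), Fndc3c1, Gap43, U90926 and Gprc5c; Fndc3c1, Gap43 and U90926 were not called with day as a factor. The lower genes included the transcription factors Tfap2b and Pitx1, the ribosomal protein gene Rpl39l and the secreted phospholipase Pla2g7. Pla2g7 was at 41.8 ± 12.2 CPM in WT and 1.44 ± 0.13 in KO (-4.87 ± 0.25). Tfap2b had 783 counts in WT against 1 in KO, a ratio of 623 with a counting interval of 111 to 24620. Agtr2, Gpr149, Wnt4, Ifi27l2b and Hoxc10 were also among the largest, with log2 fold changes from -5.60 to -5.10. Of the 20 largest differences, the calls of 16 were lost without KO day 36, 14 without KO day 42, 12 without WT day 33, 6 without WT day 36, 4 without WT day 42 and 3 without KO day 33.

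Among the remaining lists over the 3 days, mitochondrially encoded transcripts had a median of -1.16 over 13 genes, 0 of them called (camera adjusted p = 0.00128, and adjusted p = 0.81 with an estimated correlation). Their log2 values on single days were -0.67, -2.27 and -0.44. Members called in the other lists were Ddit3 (-0.87 ± 0.17) and Nupr1 (-0.83 ± 0.17, not called with day as a factor) of 26 unfolded protein and integrated stress response genes (camera adjusted p = 0.251, as given in parentheses for the lists that follow), Lpl (-3.17 ± 0.53) of 4 adipocyte markers (0.0856), Comp (2.47 ± 0.43) and Sox9 (0.92 ± 0.16) of 7 cartilage and bone markers (0.229), and Gap43 (3.46 ± 0.70) of 8 neural and glial markers (0.50). Calls were 0 by edgeR in 25 cholesterol synthesis genes (0.0731), 29 glycolysis and hypoxia genes (0.0614), 18 immediate early genes (0.907; median -0.14, camera upward), 16 macrophage markers (0.0886), 7 endothelial (0.907), 5 epithelial (0.873) and 8 skeletal muscle markers (0.312), and 4 genes that vary between C57BL/6 substrains (0.873). Unadjusted p lay below 0.05 for 10 mitochondrially encoded, 7 glycolysis, 4 endothelial and 2 skeletal muscle genes, for 1 gene each of the cholesterol synthesis, immediate early and epithelial lists, and for 0 macrophage markers and 0 substrain genes. DESeq2 called 7 mitochondrially encoded, 4 glycolysis, 2 endothelial, 2 skeletal muscle and 1 cholesterol synthesis gene and 0 in the other lists just named. Adjusted over the list alone, the numbers for these remaining lists differed from those over all genes for the endothelial markers, with 2 higher and 2 lower. Of the substrain genes, Nnt was at 117 ± 7.50 CPM in WT and 117 ± 3.88 in KO, and Wdfy1 at 141 ± 16.6 and 121 ± 10.7.

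On single days the genotypes differed at least 2-fold for 293 higher and 486 lower genes on day 33 (of 11854), 350 and 552 on day 36 (of 11816) and 364 and 781 on day 42 (of 12023). These numbers rest on 1 library per genotype and have no replicate check. On day 33 the largest higher genes were Xist, Chodl, Foxd1, Col2a1 and Nkx3-2, with Col2a1, the main cartilage collagen, at 1090 CPM in KO against 51.7 in WT, and the largest lower ones included Rpl39l, Gpr149, Tfap2b and C77370. On day 36 the largest higher genes included Xist, Fndc3c1, U90926 and Sim2, and Pitx1, Lyz1, Hoxa11os, Uts2b and Hoxa13 were lowest. Of 16 macrophage markers, 10, 13 and 9 were at least 2-fold lower in KO on days 33, 36 and 42. On day 42 Lad1, Mycn, Fndc3c1 and Pkp1 followed Xist, and the patterning genes Hoxd13 and Hoxa13, Tnn, Penk and Tfap2b were lowest, with Penk, which encodes enkephalins, at 176 CPM in WT and 0.406 in KO. The genes shared by days 33 and 36 were 134 higher and 262 lower (6.82 and 19.1 by independent lists), by days 36 and 42 152 and 330 (10.2 and 25.1), and by days 33 and 42 85 and 264 (7.22 and 23.0).

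**Figure D2:**
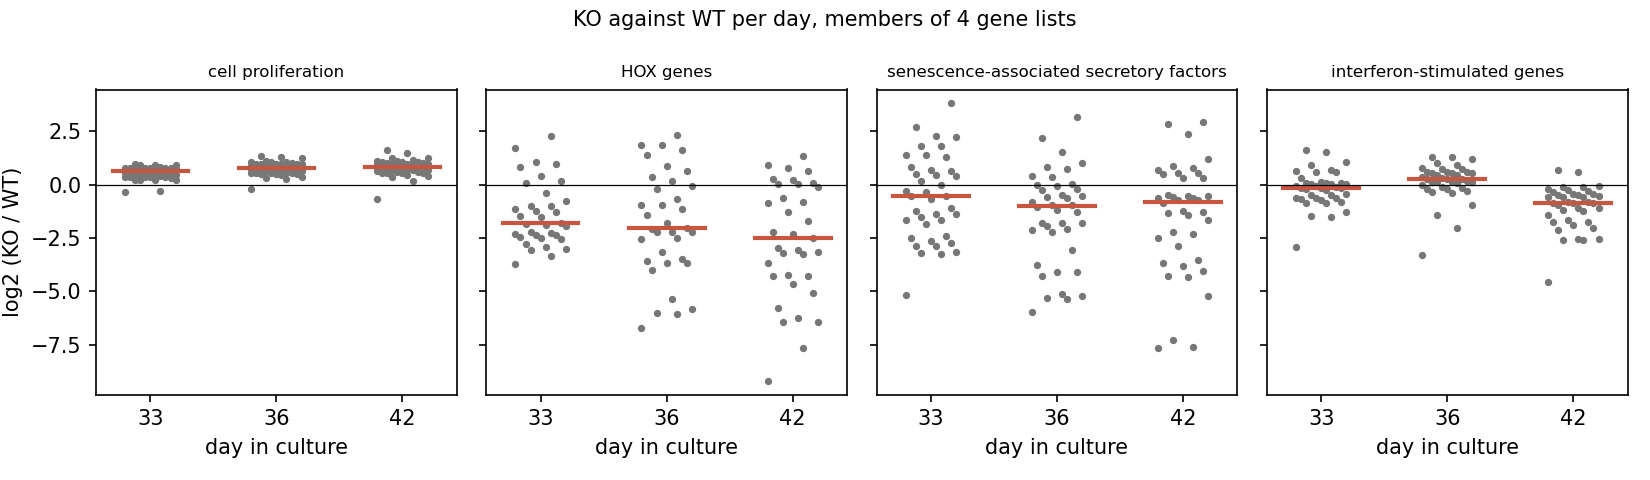
Log2 difference KO over WT (vertical axis, shared) for each measured member (grey points) of 4 gene lists on each day in culture (horizontal axis); the red bar is the median over members and each difference is between 1 library and 1 library. The proliferation medians are 0.61, 0.76 and 0.82, the HOX medians -1.79, -2.06 and -2.52, and those of interferon-stimulated genes -0.16, 0.27 and -0.85.

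The lists were also compared day by day. On day 42, 16 of 39 interferon-stimulated genes were at least 2-fold lower in KO and 0 higher (median -0.85, percentile 0), whereas on day 36 the median was 0.27 (percentile 99.9) and on day 33 -0.16 (percentile 2.36). Secreted factors had medians of -0.54, -1.0 and -0.81 on days 33, 36 and 42 (percentile 0 each). Immediate early genes had medians of 0.26, -0.79 and 0.46.

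With time in culture, WT cells differed from day 33 at least 2-fold for 38 higher and 116 lower genes on day 36, and for 359 and 248 on day 42. Macrophage genes led the lower ones on both days: C1qa, a complement component made by macrophages, was at 10.7, 1.38 and 0.086 CPM on days 33, 36 and 42, and Fcrls, Stab1, Ctss, C1qc and Adgre1 were also among the lowest, as were Agtr2 and Lum on day 36. The higher ones on day 36 were Myct1, P2ry14, Tmtc1, Apol8 and the stress factor Atf3 (10.8 to 42.9 CPM, and 3.33 on day 42). On day 42 they were Chodl, Gprin3, Agt, Tmtc1 and Fmo2, with Agt, angiotensinogen, at 0.299 CPM on day 33 and 5.70 on day 42. Interferon-stimulated genes had a median of -0.43 on day 36 (percentile 0) and 0.68 on day 42 (percentile 100), with 34 of 39 members higher and 11 at least 2-fold higher on day 42. Lgals3bp was at 72.9, 47.9 and 108 CPM.

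KO cells differed from day 33 for 127 higher and 272 lower genes on day 36, and for 170 and 306 on day 42. Lyz2, the macrophage lysozyme, was at 28.2, 0.075 and 0 CPM, and Mpeg1 at 10.6, 0 and 0.025; the near-identical Lyz1 cannot be separated from Lyz2. Hoxd13 was at 9.10, 0.037 and 0 CPM, the collagenase Mmp13 at 8.95, 0 and 0.101, and Zic1 at 7.75, 0.037 and 0. The higher genes were Crabp1, a retinoic acid binding protein (2.84, 50.3 and 30.1 CPM), Mycn, a MYC family factor (0.778, 12.8 and 15 CPM), Hs3st3a1 and Lad1 on both days, Asb5 on day 36 and Slc14a1 on day 42. Secreted factors had medians of -0.76 and -0.95 (percentile 0 each), against -0.09 and -0.26 in WT (percentiles 0.18 and 0.1), and proliferation genes 0.16 and 0.20 (percentile 100 each), against -0.02 and -0.03 in WT (percentiles 12.3 and 49.6).

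**Figure D3:**
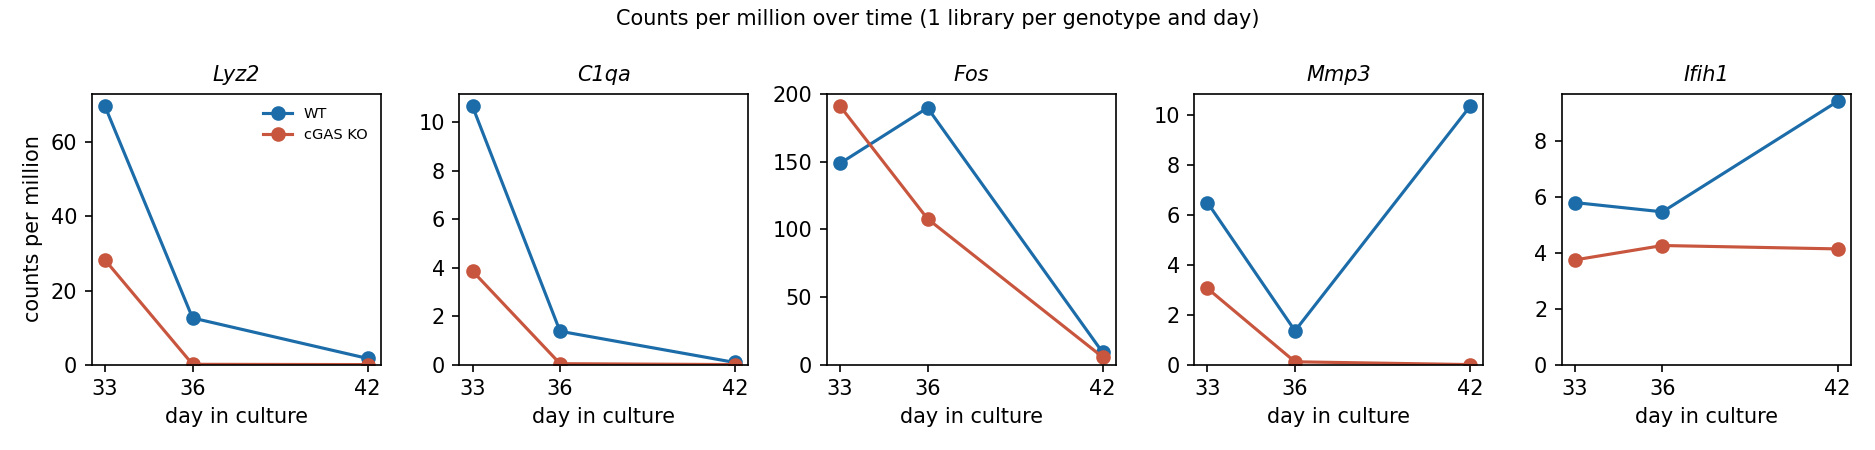
CPM (vertical axes, from 0) of Lyz2, C1qa, Fos, Mmp3 and Ifih1 against the day in culture, 1 point per library, WT in blue and KO in red, without error bars. Lyz2 is at 69.7, 12.6 and 1.66 in WT and 28.2, 0.075 and 0 in KO, and Fos at 149, 190 and 9.09 in WT and 191, 108 and 5.60 in KO.

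The change with time was also compared between genotypes, again with 1 library for each of the 4 values. Both time spans start from the same day 33 libraries, so genes found for both days are not independent findings. The same holds for genes named on both days within a genotype. From day 33 to day 36, 235 genes moved at least 2-fold more upward and 366 at least 2-fold more downward in KO than in WT, and from day 33 to day 42, 307 and 665. Crabp1, C77370 and Mycn were among the largest upward ones for both days, with Slc14a1 and Fndc3c1 for day 36 and F2rl1 and Hs3st3a1 for day 42. Tmtc1 and Zic1 were among the largest downward ones for both days, with Mmp13, Lyz1 and Lyz2 for day 36 and Hoxd13, Gprin3 and Tnn for day 42. Genes at least 2-fold higher on day 42 than on day 33 in both genotypes numbered 29 (2.99 by independent lists) and those lower 47 (4.72). With day as a factor over both genotypes, edgeR and limma-voom called 0 genes for either day. The unadjusted p lay below 0.05 for 482 genes on day 36 and 2018 on day 42 by edgeR (491 and 2109 by limma-voom), and DESeq2 called 36 and 296.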

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

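All tests of explanations in this part were chosen after the result was seen, except the count of other splits of the libraries. The 8 list differences given first were picked for opposite directions with time in WT and KO, with both medians at least 0.2 from 0 and at least 5 genes measured; these limits were set after the data were seen, each rests on 1 library per genotype and day, and the differences were not tested. Each difference is of the list medians, followed by the median of the members' own differences.

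From day 33 to day 42, interferon-stimulated genes had a median log2 difference of 0.68 in WT (34 of 39 higher) and -0.23 in KO (12 of 39 higher), a difference of -0.907 (members -0.63). Extracellular matrix genes had medians of 0.25 in WT and -0.24 in KO, a difference of -0.495 (members -0.40). The 5 epithelial markers had medians of -1.15 and 0.25, a difference of 1.4 (members 1.43). Neural and glial markers, 8 genes, had medians of -0.55 and 1.22, a difference of 1.77 (members 1.05), and to day 36 of -0.44 and 1.17, a difference of 1.61 (members 0.79). From day 33 to day 36 mitochondrially encoded transcripts had medians of 0.45 in WT and -1.08 in KO, a difference of -1.53 (members -1.60), immediate early genes 0.29 and -0.62, a difference of -0.909 (members -0.86), and contractile genes 0.24 and -0.21, a difference of -0.448 (members -0.59).

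The genotype difference of 1503 genes was set against other explanations. X and Y gene dosage of embryos of different sex, a candidate explanation for Xist and the Y-linked genes, cannot be told apart by position: 94.8% of the called genes (1425) lie outside X and Y, as do 94.7% of all genes tested (16323), and position says nothing about effects of sex on autosomal genes. The KO libraries held both Xist (465 to 641 CPM) and Y-linked transcripts (Ddx3y at 38.3 to 45.0 CPM), so they may be a mix of male and female cells, which was not tested. By summed counts Ddx3y was 3.66-fold lower in KO, Kdm5d 5.54-fold, Eif2s3y 9.46-fold and Uty 11.0-fold. A single share of male cells with the expression of WT would lower these genes alike, so a mix alone does not account for the values. Fibroblasts from another body region in the KO cultures may account for part: 57.1% of measured HOX genes were called against 8.72% of all genes, but each genotype may come from 1 source of cells, so that region, embryo sex and cGAS itself cannot be told apart. Of the 10 splits of the 6 libraries into 3 and 3, 1, the genotypes, gave as many calls, and the highest other gave 0; 10 splits are too few for a share under 0.05. The loss of cGAS remains an open, untested explanation.

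Macrophage markers were lower with time in both genotypes. At day 42, 16 of 16 markers were at least 2-fold lower than at day 33 in WT and 15 of 16 in KO (93.8%), which is what fewer macrophages in the later cultures would give. A lower depth of the later library is argued against by the total itself only for KO at day 42, where it was 108% of the day 33 total. In WT it was 71.9%, and the KO library of day 36 held 25650577 counts against 33635944 on day 33. The values are scaled to the library total, and even unscaled these totals would lower counts by less than 2-fold. The list median was -5.26 from day 33 to day 42 in WT and -5.12 from day 33 to day 36 in KO. These values argue against depth as the cause in those libraries too. Macrophages may thus have been carried over from the embryos and lost on passage, a hypothesis found and tested on the same data; a fall of these genes within other cells stays open.

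Immediate early genes were lower at day 42 in both genotypes, by medians of -1.38 in WT and -1.35 in KO. Loss of macrophages could contribute. In KO, 13 of 16 macrophage markers were at least 2-fold lower on day 36 than on day 33. From day 36 to day 42 the immediate early median in KO moved by -0.545 with 15 of 18 members lower. Fos was at 108 CPM on day 36 and 5.60 on day 42. The macrophage median in KO moved by -0.765 over the same days, but markers such as Lyz2 were already almost absent on day 36. That median may therefore lean on the prior count, and a further loss of macrophages is neither shown nor set aside. In WT from day 33 to day 36 the macrophage median moved by -2.275, with 14 of 16 markers at least 2-fold lower. The immediate early median there was 0.29 with 13 of 18 members higher, which a loss of macrophages alone would not give. This rests on 1 library per day and leaves the question open. Handling at the day 42 harvest might also lower these rapidly induced genes in both genotypes, and it cannot be told apart from the day itself.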

How the results depend on the processing

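The fit of 24 columns was the design written before the data were seen. The fit of 6 summed libraries, day as a factor and the test of time over both genotypes were chosen afterwards; the other settings were written before, for 24 libraries. The number of genes called between KO and WT was 2855 by DESeq2, 429 without day 33, 3 without day 36 and 539 without day 42. Leaving out 1 library gave 24 to 1811, and 24 to 738 where the count fell by over 1.5 times. It was 1475 by limma-voom, 1501 with RLE size factors, 1266 without a filter, 1131 with a mean of at least 5 CPM (53.4% higher, against 46.6%) and 1338 with day as a factor, which kept 1063 of the 1503 calls and lost 440. Among genes named over the 3 days, day as a factor ended the calls of 11: Fndc3c1, Gap43, U90926, Banf1, Mavs, Nlrc3, Perp, Ercc5, Ephx1, Col12a1 and Nupr1. Fewer libraries leave fewer degrees of freedom, but all fits without 1 library lose the same number, so this does not account for the uneven losses. The most alike libraries were WT days 33 and 36 (r = 0.991 of log2 CPM) and KO days 36 and 42 (r = 0.991). The count fell where any of these was left out and rose without WT day 42 or KO day 33. The cause was not tested.

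The deposited columns taken as separate libraries gave 11107 calls, 11103 with a replicate block, and 11758 when summed over days into 4 against 4. Taking repeated columns of 1 library as replicates makes these numbers too high by construction. Columns of the same number did not deviate together over genes (r from -0.035 to 0.042), so no shared deviation per gene was seen. Their totals did follow the number in all 6 groups, so the numbers may still tie columns across groups. By adjusted p alone the 24 columns gave 8347, 9234 and 10444 genes between genotypes on days 33, 36 and 42, 5384 and 9501 for days 36 and 42 in WT, 6086 and 8174 in KO, and 5742 and 7807 for the difference between genotypes. Under every other setting run, the counts of 2-fold differences between single libraries stayed within 1.5 times. Values of named genes between single libraries were checked only with RLE size factors, without a filter and with only the groups compared. Of these values, 225 of 225 stayed within counting error. Those settings change little but the scaling, so the check could hardly have failed. Lists called by camera were 9 with the preset correlation and 0 with an estimated one. For single transcripts and chromosome shifts the exact test of 3 against 3 has a smallest p of 0.1, so no setting could call any.

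No gene called over the 3 days changed sign, which was nearly certain because the other settings reuse the same libraries. Of genes not called, the log2 fold change of Il6 (0.47) was -0.62 by limma-voom, -1.59 without day 33, -0.49 with day as a factor, and -0.58 with the 24 columns, also with the replicate block (-0.58). Without day 33, Fosl2 was at -0.0013 and Cdh1 at 0.067. Without day 42, Isg15 was at 0.47, Nnt at 0.081, Myh8 at 0.061, Pparg at 0.15 and Cebpa at 0.31. Leaving out 1 library gave -1.57 to 1.01 for Il6, -0.78 to 0.25 for Isg15, -0.035 to 0.054 for Nnt, -1.32 to 0.044 for Cebpa, -0.20 to 0.023 for Entpd4, -1.36 to 0.071 for Cd68 and -3.73 to 0.17 for Fcer1g. Nnt was at 0.0075 when summed over days. The cause was not tested. Low counts limit Mb21d1, Isg15, Il6 and Cxcl10. They also limit 2 called genes, Ifi27l2a (135 counts in WT and 8 in KO, summed over days) and Hoxd1 (64 and 6).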

Other observations

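Cholesterol synthesis and glycolysis genes were lower on day 42 than on day 33 in both genotypes. From day 33 to day 42, 23 of 25 cholesterol synthesis genes were lower in WT (median log2 -0.45) and 24 of 25 in KO (-0.66), both at percentile 0. Of 29 glycolysis and hypoxia genes, 28 were lower in WT (median -0.62) and 24 in KO (-0.51), again at percentile 0. On day 36 the cholesterol list had medians of -0.099 in WT and 0.22 in KO (21 of 25 higher, percentile 100), and the glycolysis list 0.031 in WT (18 of 29 higher, percentile 68.2) and -0.18 in KO. Each value compares 1 library with 1 library, and by edgeR the test of time over both genotypes called 0 genes for day 42, with 2018 at an unadjusted p below 0.05 and 296 called by DESeq2.

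Some transcripts were more abundant in the KO library of day 33 than in the later KO libraries. Foxd1, a transcription factor of kidney stroma, was at 20.5, 1.75 and 1.22 CPM on days 33, 36 and 42, Tmtc1 at 78.7, 3.54 and 7.63 CPM, and Col2a1 at 1090, 130 and 91.4 CPM. Adipocyte markers, 4 genes, had medians of -1.98 from day 33 to day 36 and -1.54 to day 42 in KO, against -0.72 and 0.16 in WT.

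The chromosomes were compared for shifts between the genotypes. By the exact permutation test of 3 libraries against 3, with a smallest p of 0.1, 0 chromosomes reached an adjusted p of 0.05, which this test cannot reach. Within 5 Mb of Mb21d1, 5 of 50 genes were called (10%) against 8.71% elsewhere (two-sided Fisher's exact p = 0.621). Within 1 Mb, 1 of 15 genes was called (6.67%), and that gene was Gsta4. Col12a1 (from 79598991) lies within 5 Mb. These shares cannot exclude an effect of the targeted locus on single neighbours, which was not tested.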
